A study of Mus musculus with 15 samples.

How the data were processed

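The series holds 15 arrays of biotin-labelled total RNA from mouse aorta, amplified with the NuGEN Applause WT-Amp Plus ST system per the labels. The deposited values, 1 per probe set and array, were taken as log2 intensities normalised with RMA. The submitters' processing notes name RMA and Partek, with no version, role or order. The log base is not stated and was inferred from the range of the values, 1.381 to 13.33. Array medians lay between 5.778 and 5.84. No raw images, scan dates or detection calls were available, so batches could not be looked for by date, and signal over background is unknown. Pearson's r between arrays of 1 group, across probe sets, was 0.9739 to 0.9885.

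The table holds 41345 probe sets. The gene table lists 25335 of them, of which 23521 name exactly 1 gene symbol and 1814 several, and 16010 are unnamed there. Of those with 1 symbol 23328 matched a RefSeq symbol, and 0 symbols were updated. For the 1082 genes with several probe sets the one with the highest mean over all arrays was used, which left 22180 genes, and no dim genes were removed. Other probe sets of called genes had the opposite sign in 21 of 140 cases in the abdominal diet change, 3 of 43 in the thoracic one and 25 of 212 in the average. Between segments they had it in 13 of 88 under chow and 39 of 309 under high phosphate. Of these 0, 0, 3, 0 and 16 had p under 0.05. Probe sets without a single gene were tested apart.

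Arrays were grouped by segment and diet from their titles. Replicate numbers were not treated as pairs, and the labels do not say whether both segments came from the same mice. The design, gene lists, tests, rule for named genes and alternatives were chosen before the data were examined, apart from those said below to be added. A linear model with 4 group means was fitted with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend), with 11 residual degrees of freedom and a median prior of 3.901. It gave 6 contrasts. These were the diet change in each segment (high phosphate minus chow), their average, their difference (abdominal minus thoracic), and the difference between segments on each diet (thoracic minus abdominal). Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all genes, two-sided. Tables were handled with the data.table package, version 1.17.8, and plots drawn with matplotlib 3.10.9.

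Of 43 gene lists fixed, 25 are pathway lists, 17 are cell type lists and 1 checks sex-linked genes. The 42 lists with at least 3 measured members were tested with limma's camera at a preset correlation of 0.01, Benjamini-Hochberg adjusted over the lists of a contrast, and the list of erythrocyte genes, with 2 measured members, was not tested. Camera with an estimated correlation between genes and the rotation test fry were run beside it. Calls are given over all genes and adjusted over the list alone. Some list members were not analysed here, and each list is described by its measured members. Lists share members, such as Lum and Lyve1, each in 2 of them. Lists of hepatocyte genes and of targets of FoxO transcription factors were added after the data were seen.

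Genes were named by a rule. For the diet change in each segment, its average and the chow comparison of segments, these were the 10 largest rises and 10 largest falls among called genes whose groups do not overlap. For the other contrasts they were the 5 genes with the smallest p in each direction. For each list up to 4 members with the smallest p were allowed, and any member of the lists on phosphate transport, calcification inhibitors and osteochondrogenic genes could be named. Symbols of predicted genes and of some gene classes were counted and not named. Not every gene the rule allows is named.

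The alternatives changed 1 choice at a time, apart from the rule of unadjusted p with 1.5-fold change, which changed 2. They were a variance prior without trend, removal of genes below the 30th percentile of mean intensity, a fit with only the groups compared, quantile normalization, median centring, array weights and a replicate block. Further ones were the mean of a gene's probe sets, the pan-adipocyte and brown adipocyte list means as covariates, an adjusted p under 0.1, a rule of unadjusted p under 0.05 with 1.5-fold change, and leaving out each array in turn. Added after seeing the data were a fit without the 5 abdominal arrays whose T and NK cell mean was high, a fit without abdominal high-phosphate arrays 3 and 4, and the mean of the lymphocyte lists as a covariate.

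The pipeline was tested on simulated data with the means and spreads of these arrays, in which 200 genes were changed. Noise was drawn independently for each gene with the same spread in every group. The real groups differ in spread and their genes vary together, so the rates below need not hold for these data. Of genes changed by 0.5 on the log2 scale 43.28% were recovered in the abdominal and 44.78% in the thoracic diet contrast, of those changed by 1 95.52% and 91.04%, and of those changed by 2 all. In these contrasts 11 of 170 and 2 of 159 calls were false.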

Results

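Gene expression was measured on 15 arrays of total RNA from mouse aorta, 8 from the abdominal and 7 from the thoracic segment. The mice were of the inbred strain DBA/2NCrl, were 8 weeks old at the start, and ate for 5 days either a high-phosphate diet with 20.2 g of phosphorus per kg or standard chow with 7.0 g per kg. The groups held 4 abdominal high-phosphate arrays, 4 abdominal chow arrays, 3 thoracic high-phosphate arrays and 4 thoracic chow arrays, described as biological replicates. The number of arrays limits the precision of every value, and no read or spot counts were available. The labels give no sex. In every array Xist, transcribed from the inactive X chromosome, lay between 11.55 and 11.98 on the log2 scale, and the Y-linked genes Eif2s3y, Kdm5d and Uty lay between 2.63 and 3.35. The study asks how a phosphate-rich diet changes gene expression in the aorta. Below, values are mean log2 intensity ± SD over the arrays of a group, and changes are log2 differences ± SE from limma.

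Markers of neighbouring tissues differed between arrays. The mean of 15 sympathetic neuron and chromaffin genes was 9.06 in the abdominal high-phosphate and 8.82 in the abdominal chow group, against 6.03 and 5.70 in the thoracic groups, with thoracic high-phosphate array 2 at 6.79. The mean of 14 cardiac muscle genes was 7.84 and 7.62 in the thoracic high-phosphate and chow groups, against 5.8 and 5.90 in the abdominal ones. The mean of 13 T and NK cell genes was 7.52, 7.52 and 7.16 in abdominal high-phosphate arrays 1, 2 and 4. It was 6.93 and 7.45 in abdominal chow arrays 2 and 4, and none of the other arrays passed 5.82. Glycam1, a ligand made by lymph node vessels, lay between 12.59 and 12.78 in these 5 arrays. It was nearly as high in high-phosphate array 3 (12.20) and chow array 3 (12.17), against 8.95 in chow array 1 and 6.28 to 6.76 in thoracic arrays. A fit without the 5 arrays may therefore still hold lymph node tissue. The mean of 11 hepatocyte genes, a list chosen after the values of the liver gene Ahsg were seen, was 8.36 and 10.2 in abdominal high-phosphate arrays 3 and 4 and 6.65 in thoracic chow array 4, against 5.18 to 5.97 in the others. The mean of 12 brown adipocyte genes, a list named for the fat that produces heat, was above 7 in every array. Its members need not be made by that fat alone.

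**Figure D1:**
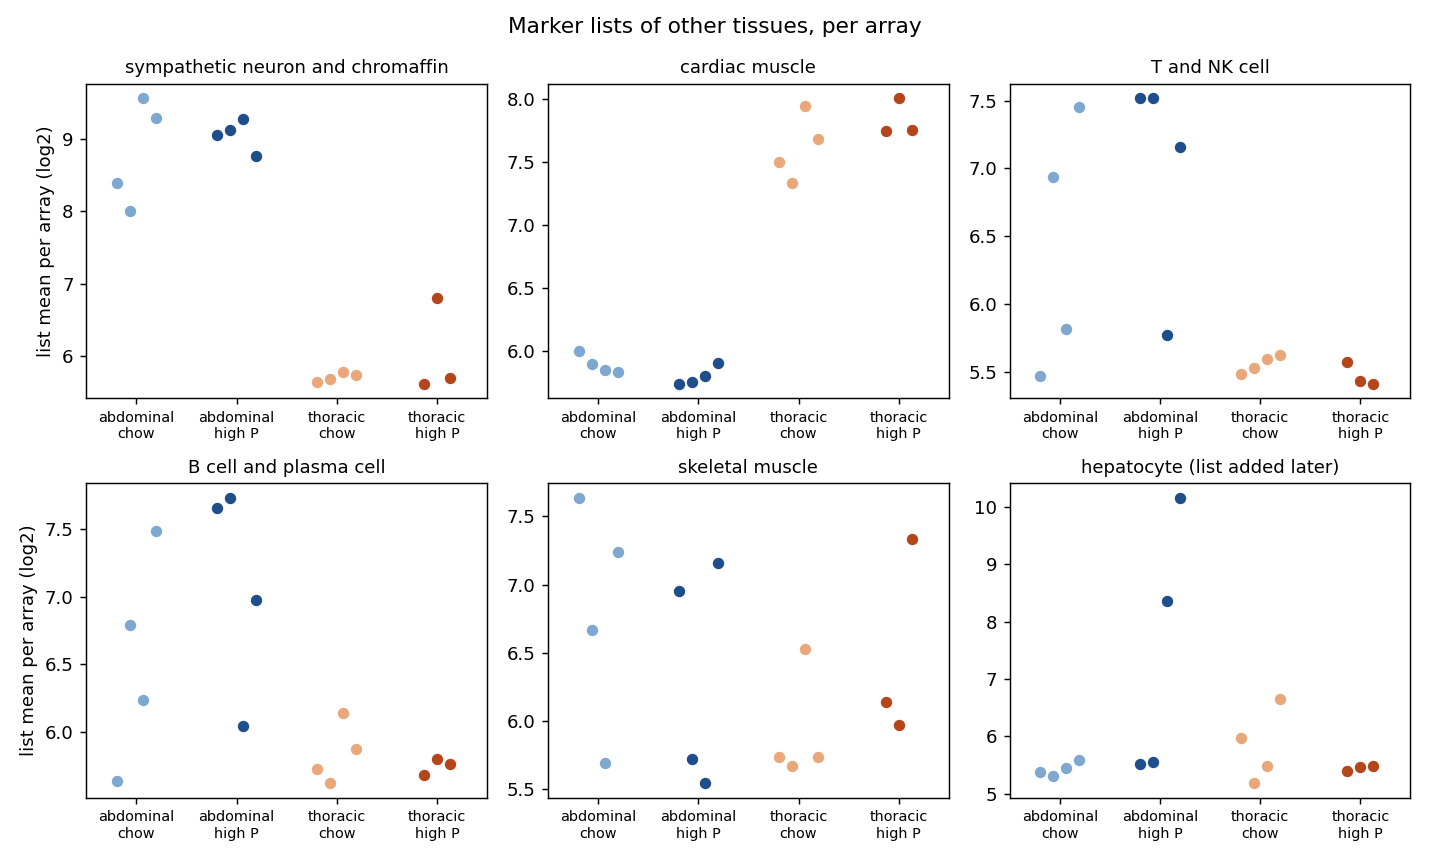
Mean log2 intensity of the members of 6 marker lists (vertical axes) by segment and diet (horizontal axes), with 1 point per array; high P is the high-phosphate diet. Neuron markers are high in the abdominal arrays and cardiac markers in the thoracic arrays. Lymphocyte markers are high in most abdominal arrays, and skeletal muscle and hepatocyte markers in some arrays.

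The abdominal comparison asks what the high-phosphate diet changed in that segment. The largest fall was that of Ucp1, the uncoupling protein by which brown adipocytes make heat (probe set 17502899), from 11.56 ± 0.21 on chow (n = 4) to 7.95 ± 0.94 (n = 4), 12.2-fold lower. Cox7a1, a subunit of cytochrome c oxidase, fell by 2.51 ± 0.217. Agpat2, an enzyme of triglyceride synthesis, fell by 2.31 ± 0.188. Fkbp5, an immunophilin induced by glucocorticoids (probe set 17342868), rose from 6.17 ± 0.25 to 7.96 ± 0.14, 3.46-fold, and Fam107a rose by 2.03 ± 0.215.

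The other genes with the largest rises were Cyp2b10, a cytochrome P450 (1.78 ± 0.298), the metallothionein Mt2 (1.65 ± 0.233), the methyltransferase Inmt (1.56 ± 0.176), and Trp53inp1, a p53 target (1.53 ± 0.156). Further rises were those of the serpin Serpina3n (1.504 ± 0.384), the amino acid transporter Slc7a8 (1.39 ± 0.279), Depp1, a FoxO target (1.38 ± 0.197), and Il22ra2, a decoy receptor for interleukin-22 (1.32 ± 0.34). The other large falls were those of Lncbate10, a long noncoding RNA of brown fat (-2.29 ± 0.443), the fatty acid synthase gene Fasn (-2.09 ± 0.458), Prkar2b, a regulatory subunit of protein kinase A (-1.88 ± 0.271), and Hcar1, the lactate receptor of adipocytes (-1.83 ± 0.172). Further falls were those of the retinol dehydrogenase Dhrs9 (-1.83 ± 0.252), the kallikrein Klk1 (-1.76 ± 0.265) and the acute-phase gene Orm3 (-1.75 ± 0.169).

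Among the gene lists, those of mitochondrial and adipocyte metabolism fell most. Of 28 oxidative phosphorylation genes, 27 fell (27 adjusted over the list alone). Their mean change was -0.74, and they included the complex I subunits Ndufa1 (-1.19 ± 0.114) and Ndufa9 (-0.93 ± 0.0835); camera gave an adjusted p of 1.21e-39, and adjusted p = 0.0875 with an estimated correlation. Of 18 fatty acid oxidation genes 16 fell (17 adjusted over the list alone). They included Hadha (-1.35 ± 0.14) and Acaa2 (-1.40 ± 0.146), enzymes of mitochondrial beta-oxidation (adjusted p = 7.38e-22, and adjusted p = 0.148 with an estimated correlation). Of 12 brown adipocyte genes 10 fell (10 adjusted over the list alone). Their mean change was -1.37, and Cox8b was among them (-1.65 ± 0.133) (adjusted p = 4.74e-13, and adjusted p = 0.081 with an estimated correlation). Of 16 genes of de novo lipogenesis 9 fell (13 adjusted over the list alone). They included Dgat2, which forms triglycerides (-1.52 ± 0.235), and the elongase Elovl5 (-0.62 ± 0.0946) (adjusted p = 3.18e-11, and adjusted p = 0.188 with an estimated correlation). Of 15 pan-adipocyte genes 7 fell (11 adjusted over the list alone). They included the lipid droplet coat gene Plin1 (-1.71 ± 0.219) and the hormone gene Retn (-1.56 ± 0.181) (adjusted p = 5.22e-11, and adjusted p = 0.188 with an estimated correlation).

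**Figure D2:**
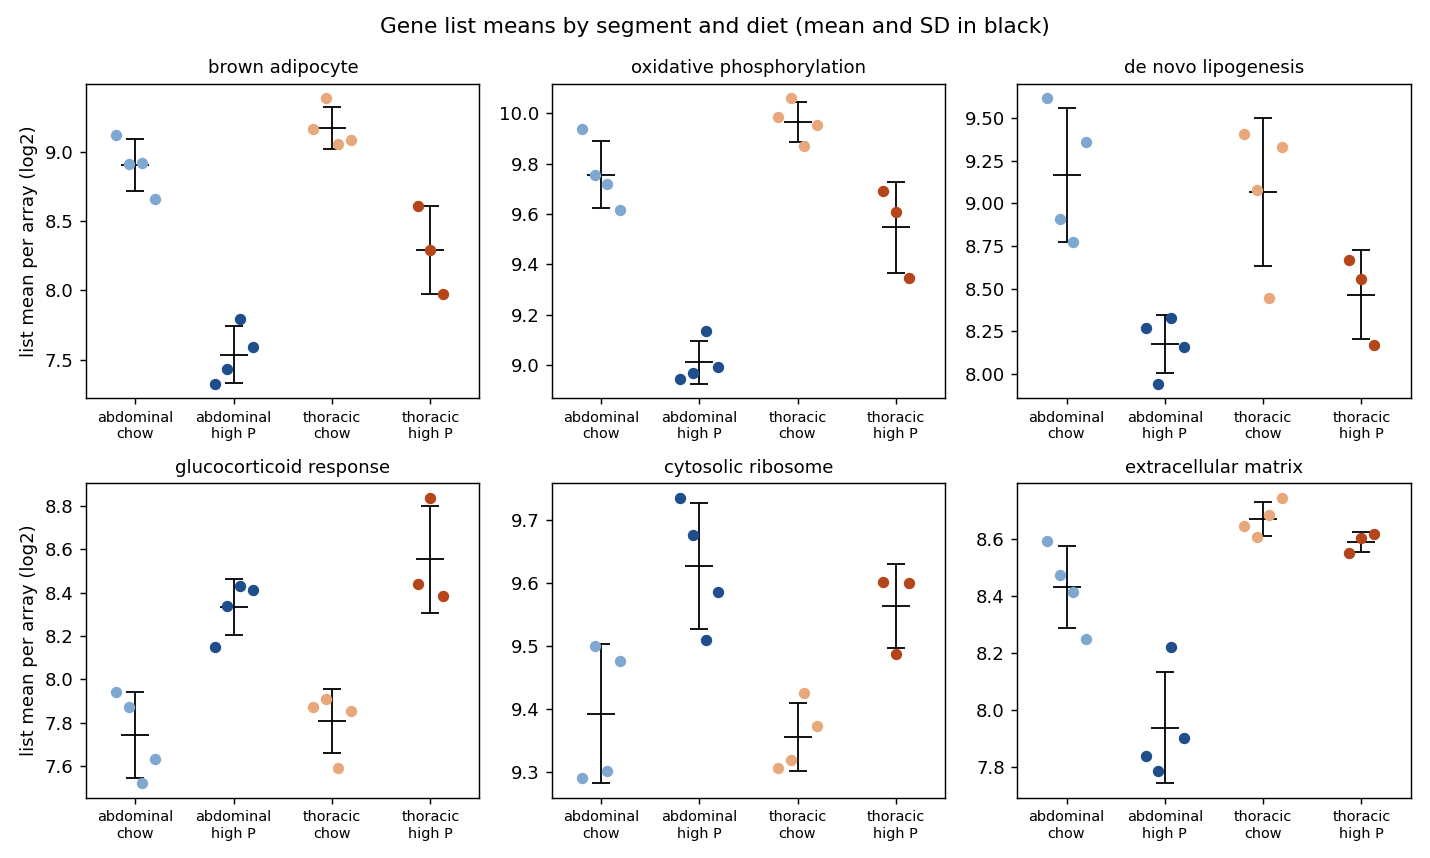
Mean log2 intensity of the members of 6 gene lists (vertical axes) by segment and diet (horizontal axes), with 1 point per array and the group mean and SD in black; high P is the high-phosphate diet. The brown adipocyte means of the abdominal groups are 8.90 on chow and 7.54 on high phosphate, and those of the thoracic groups are 9.17 and 8.29.

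Matrix and fibroblast genes fell as well. Of 29 extracellular matrix genes 10 fell, and adjusted over the list alone 22 fell and 1 rose. They included the collagens Col3a1 (-1.39 ± 0.112) and Col6a1 (-0.91 ± 0.093) and the proteoglycan Lum (-1.502 ± 0.185); the adjusted p was 2.39e-13, and adjusted p = 0.188 with an estimated correlation. The list mean was 8.22 in high-phosphate array 3, without high lymphocyte markers, against 7.79 to 7.90 in the other 3, which have them, and 8.25 to 8.59 on chow. Without the 5 arrays with such markers, which left array 3 as the only high-phosphate array, the change moved from -0.49 to -0.282. That array had a hepatocyte mean of 8.36 and the lymph node vessel gene Glycam1 at 12.20, so it is not free of other tissue. Of 14 adventitial fibroblast genes 4 fell, namely Dpt (-1.11 ± 0.122), Lum, Cd34 (-0.78 ± 0.103) and Pi16 (-0.80 ± 0.138), and the peptidase Dpep1, named after its values were seen, rose (1.01 ± 0.207). Adjusted over the list alone 7 fell and 1 rose (adjusted p = 0.000293, and adjusted p = 0.212 with an estimated correlation). Of 15 cholesterol synthesis genes 4 fell (4 adjusted over the list alone). They were Insig1, a brake on sterol synthesis (-1.10 ± 0.142), Hmgcs1, which makes the precursor of mevalonate (-0.86 ± 0.134), Sc5d (-0.34 ± 0.0983) and Dhcr7 (-0.33 ± 0.0953) (adjusted p = 0.00129, and adjusted p = 0.282 with an estimated correlation). Of 12 heat shock genes 3 fell (6 adjusted over the list alone). They were the chaperones Hspd1 (-0.45 ± 0.082), Hsph1 (-0.49 ± 0.119) and Cryab (-0.74 ± 0.205) (adjusted p = 0.000142, and adjusted p = 0.209 with an estimated correlation). Of 15 hypoxia and glycolysis genes 6 fell, among them Egln1, an oxygen sensor (-0.80 ± 0.127), and P4ha1, a collagen hydroxylase (-0.68 ± 0.0828), and the glucose transporter gene Slc2a1, named after its values were seen, rose (0.42 ± 0.101). Adjusted over the list alone 8 fell and 2 rose (adjusted p = 0.0104, and adjusted p = 0.308 with an estimated correlation).

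The contractile, endothelial and Wnt lists were called lower as well. Of 22 contractile genes of smooth muscle 2 fell (4 adjusted over the list alone). They were the focal adhesion gene Vcl (-0.58 ± 0.109) and Acta2, smooth muscle actin (-0.46 ± 0.125) (adjusted p = 8.2e-05, and adjusted p = 0.547 with an estimated correlation). The list mean was 8.68 in high-phosphate array 3, against 8.04 to 8.22 in the 3 with high lymphocyte markers and 8.27 to 8.78 on chow. The change of the list moved from -0.29 to -0.006 without the 5 arrays with such markers. That fit left array 3 as the only high-phosphate array, with a hepatocyte mean of 8.36. With the lymphocyte lists as a covariate the call of the smooth muscle list held. Of 17 endothelial genes, Kdr (-0.53 ± 0.135), Tek (-0.49 ± 0.129) and Sox18 (-0.52 ± 0.128) fell and Pecam1 rose (0.33 ± 0.0663), and adjusted over the list alone 8 fell and 1 rose (adjusted p = 0.0161, and adjusted p = 0.547 with an estimated correlation). Of 22 Wnt signalling genes, the secreted modulators Sfrp2 (-1.11 ± 0.135) and Sfrp4 (-1.30 ± 0.203) and the ligand Wnt5a (-0.50 ± 0.134) fell (3 adjusted over the list alone; adjusted p = 0.0383, and adjusted p = 0.285 with an estimated correlation).

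By camera's adjusted p the lists that rose were led by glucocorticoid response and ribosomal genes, though by size of change the ribosomal list did not lead. The glucocorticoid response mean was 7.74 on chow and 8.33 on high phosphate. Of 16 glucocorticoid response genes 10 rose, among them Fkbp5, Mt2 and the sulfotransferase Sult1a1 (0.78 ± 0.124), and Pdk4, a kinase that spares glucose and named after its values were seen, fell (-0.74 ± 0.184). Adjusted over the list alone 12 rose and 2 fell (adjusted p = 9.71e-09, and adjusted p = 0.188 with an estimated correlation). Of 23 genes of the cytosolic ribosome 8 rose (17 adjusted over the list alone). They included Rps9 (0.40 ± 0.0833) and Rps18 (0.28 ± 0.0605) (adjusted p = 8.92e-11, and adjusted p = 0.209 with an estimated correlation). Of 16 macrophage genes the complement gene C1qb (0.42 ± 0.103) and the hyaluronan receptor Lyve1 (0.52 ± 0.149) rose (5 adjusted over the list alone; adjusted p = 0.000491, and adjusted p = 0.392 with an estimated correlation). Of 8 lymphatic endothelial genes Lyve1 and Mmrn1 (0.80 ± 0.127) rose (5 adjusted over the list alone; adjusted p = 0.0142, and adjusted p = 0.188 with an estimated correlation). Of 18 clock genes the period gene Per1 (0.88 ± 0.212), Tef (0.62 ± 0.168) and Ciart (0.58 ± 0.137) rose and Clock fell (-0.32 ± 0.0921), and adjusted over the list alone 4 rose and 1 fell (adjusted p = 0.0382, and adjusted p = 0.579 with an estimated correlation). The other probe set of Tef (17319524) gave -0.09, and the Tef call ended with the mean of both (0.264). The T and NK cell, B and plasma cell and cell cycle lists were called higher by camera with 0 of their genes called by limma (mean changes 0.57, 0.56 and 0.19; adjusted p = 0.0141, 0.00415 and 0.00136, and adjusted p = 0.579 for each with an estimated correlation). Adjusted over the list alone, 0, 1 and 0 of their members passed. High lymphocyte markers were found in 3 of the 4 high-phosphate and 2 of the 4 chow arrays. Without these 5 arrays the cell cycle change was -0.008. With adipocyte covariates the T and NK cell, B and plasma cell and cell cycle changes were -1.991, -2.135 and -0.824.

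In all, limma called 1554 of 22180 genes in the abdominal comparison, 432 higher and 1122 lower on high phosphate, of which 30 and 118 changed at least 2-fold. Camera called 21 of 42 lists, 14 of them called by fry as well. None of the 21 held with an estimated correlation, where the lowest adjusted p was 0.081. The other 21 lists had adjusted p from 0.0633 to 0.954. The count fell to 812 under a rule of unadjusted p and 1.5-fold and to 1026 with only the abdominal groups in the fit. It fell to 891 without chow array 1 (207 higher, 684 lower) and to 1023 without high-phosphate array 2. It rose to 2249 without high-phosphate array 3 (805 higher, 1444 lower). Without high-phosphate arrays 3 and 4, the abdominal arrays with hepatocyte markers, 15 calls of genes named for this comparison ended. In that fit the count was 1732 (701 higher, 1031 lower). It fell to 137 without the 5 arrays with high lymphocyte markers, which left 1 high-phosphate and 2 chow arrays and turned the balance to 96 higher and 41 lower, and to 0 with adipocyte list means as covariates. Without the 5 arrays 57 of the 75 called genes named for this comparison lost their call. So did the heat shock, hypoxia, smooth muscle, endothelial, Wnt, macrophage, lymphatic, clock, B and plasma cell and T and NK cell lists. That fit rests on high-phosphate array 3 alone, with a hepatocyte mean of 8.36, so its counts cannot be laid to lymphocyte tissue alone. In it the Wnt, endothelial and clock changes were -0.167, -0.144 and 0.206, near or above their main sizes. The other changes were clearly smaller, such as -0.006 for smooth muscle. With 1 array left out in turn, 24 of the 75 called genes named for this comparison lost their call at least once (adjusted p up to 0.165). These were Serpina3n, Il22ra2, Acta2, Kdr, Tek, Sox18, C1qb, Lyve1, Ciart, Per1, Tef, Clock, Wnt5a, Pdk4, Slc2a1, Dhcr7, Sc5d, Hsph1, Cryab, Pth1r, Phex, Alpl, Nt5e and Cpa3. The endothelial, Wnt, clock, B and plasma cell and T and NK cell lists lost theirs too (adjusted p up to 0.187). Other probe sets gave smaller changes, such as those for Sfrp2 (-0.149), Slc2a1 (0.072), Rps18 (0.062 and 0.123) and Fam107a (1.006).

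The thoracic comparison asks the same of the other segment. Ucp1 fell there too, from 11.81 ± 0.14 on chow (n = 4) to 9.55 ± 0.74 (n = 3), 4.79-fold lower, and Lncbate10 fell by 2.28 ± 0.478. Agpat2 fell by 1.77 ± 0.203 and Cox7a1 fell by 1.45 ± 0.234. Tfrc, the transferrin receptor that takes up iron, fell by 1.72 ± 0.247, and Ucp3, an uncoupling protein of muscle and brown fat, fell by 1.62 ± 0.185. The largest rise was that of Cxcl13, a chemokine that attracts B cells (probe set 17439367; 2.20 ± 0.538). Apod, a lipid carrier of the lipocalin family, rose by 1.86 ± 0.203 and Fkbp5 by 1.68 ± 0.176.

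Other large rises were those of Slc7a8 (2.19 ± 0.302), Cyp2b10 (2.09 ± 0.322), Il22ra2 (1.80 ± 0.367), Mt2 (1.73 ± 0.251), Ms4a4a, a gene of the membrane-spanning 4A family (1.69 ± 0.211), Fam107a (1.62 ± 0.232) and Trp53inp1 (1.42 ± 0.168). Other large falls were those of Slc25a42, a mitochondrial carrier of coenzyme A (-1.46 ± 0.254), Dhrs9 (-1.41 ± 0.272), the tetraspanin Tspan18 (-1.38 ± 0.185) and Noct, a rhythmically expressed phosphatase (-1.35 ± 0.256).

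Of 28 oxidative phosphorylation genes 16 fell in the thoracic segment (26 adjusted over the list alone). They included Ndufa1 (-0.72 ± 0.123) and Ndufa9 (-0.47 ± 0.0902), with a mean change of -0.42 (adjusted p = 3.91e-25, and adjusted p = 0.216 with an estimated correlation). Of 18 fatty acid oxidation genes 6 fell (16 adjusted over the list alone). They included Cpt2, which carries fatty acids into the mitochondrial matrix (-0.96 ± 0.165), and Hadha (-0.81 ± 0.151) (adjusted p = 2.76e-15, and adjusted p = 0.242 with an estimated correlation). Of 12 brown adipocyte genes 5 fell (10 adjusted over the list alone). They were Ucp1, Cox7a1, the proton channel Otop1 (-1.15 ± 0.204), the deiodinase Dio2 (-1.02 ± 0.203) and Cox8b, named after its values were seen (-0.72 ± 0.144) (adjusted p = 6.31e-11, and adjusted p = 0.118 with an estimated correlation). Of 16 lipogenesis genes Elovl5 (-0.58 ± 0.102) and the acyltransferase Gpam (-0.68 ± 0.146) fell (6 adjusted over the list alone; adjusted p = 2.3e-06, and adjusted p = 0.525 with an estimated correlation). Of 15 pan-adipocyte genes Retn fell (-0.81 ± 0.196; 4 adjusted over the list alone; adjusted p = 0.045, and adjusted p = 0.804 with an estimated correlation). The heat shock list was called lower with 0 genes called by limma (1 adjusted over the list alone; mean change -0.20; adjusted p = 0.033, and adjusted p = 0.585 with an estimated correlation).

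Of 16 glucocorticoid response genes 8 rose, among them Fkbp5, Mt2 and Sult1a1 (1.01 ± 0.134), and adjusted over the list alone 13 rose and 1 fell (adjusted p = 1.79e-14, and adjusted p = 0.118 with an estimated correlation). Of 23 ribosomal genes 4 rose (9 adjusted over the list alone). They were Rps18 (0.39 ± 0.0654; -0.156 for probe set 17343692), Rps6 (0.28 ± 0.0563), Rpl10a (0.49 ± 0.101) and Rpl14 (0.35 ± 0.081) (adjusted p = 1.63e-09, and adjusted p = 0.371 with an estimated correlation). Of 16 macrophage genes Lyve1 rose (0.74 ± 0.161; 5 adjusted over the list alone; adjusted p = 3.88e-06, and adjusted p = 0.371 with an estimated correlation). Of 18 clock genes Ciart (0.82 ± 0.148) and the deubiquitinase Usp2 (0.79 ± 0.13) rose (6 adjusted over the list alone; adjusted p = 0.00178, and adjusted p = 0.525 with an estimated correlation). Of 21 immediate early genes Zfp36, which destabilises cytokine messages, rose (0.72 ± 0.159; 5 adjusted over the list alone; adjusted p = 0.00211, and adjusted p = 0.525 with an estimated correlation). The skeletal muscle list was called higher with 0 of its genes called by limma (mean change 0.56; adjusted p = 0.049, and adjusted p = 0.804 with an estimated correlation), and its mean per array was 7.33 in high-phosphate array 3 against 6.14 and 5.97 in the other two.

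In all, limma called 548 genes in the thoracic comparison, 309 higher and 239 lower, of which 42 and 25 changed at least 2-fold. Camera called 12 of 42 lists, 4 of them called by fry as well. None of the 12 held with an estimated correlation (lowest adjusted p = 0.118), and the other 30 had adjusted p from 0.0547 to 0.92. The count moved to 992 at an adjusted p under 0.1, to 907 with array weights, to 990 with lymphocyte list means as a covariate and to 0 with adipocyte list means as covariates. It fell to 209 without chow array 1, 327 without chow array 2, 265 without chow array 4, 245 without high-phosphate array 2 and 263 without high-phosphate array 3. The balance turned with quantile normalization (301 higher, 315 lower) and without high-phosphate array 1 (199 higher, 289 lower). With 1 array left out in turn, 19 of the 45 called genes named for this comparison lost their call at least once (adjusted p up to 0.187). These were Cxcl13, Il22ra2, Lncbate10, Dhrs9, Noct, Ndufa9, Gpam, Rps6, Rpl10a, Rpl14, Lyve1, Zfp36, Retn, Dio2, Cox8b, Fdft1, Sfrp2, Col3a1 and Thbs1. The immediate early, heat shock, pan-adipocyte and skeletal muscle lists lost theirs too (adjusted p up to 0.79). Other probe sets gave smaller changes, such as those for Dio2 (-0.364), Fam107a (0.531) and Rps18 (0.047, beside the one of opposite sign).

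Because phosphate excess is linked to calcification of the vessel wall, 3 lists on that subject had been fixed. None was called by camera in either segment. The adjusted p for 18 genes of phosphate transport and hormone response was 0.446 in the abdominal and 0.677 in the thoracic segment. That for 14 pyrophosphate and calcification inhibitor genes was 0.675 and 0.54. That for 20 osteochondrogenic genes was 0.588 and 0.879. A further 3 inhibitor genes and 4 osteochondrogenic genes of these lists were not analysed here. Single members were called in the abdominal segment. Pth1r, a receptor of parathyroid hormone, fell by 0.43 ± 0.105 (adjusted p = 0.0198). Phex, a protease that restrains the phosphate hormone FGF23, fell by 0.62 ± 0.155 (adjusted p = 0.0239). Alpl, the phosphatase that degrades pyrophosphate, fell by 0.41 ± 0.104 (adjusted p = 0.0246). Nt5e, which makes adenosine from AMP, rose by 0.36 ± 0.0909 (adjusted p = 0.0239). Their thoracic changes were -0.29 ± 0.113 for Pth1r, -0.38 ± 0.167 for Phex, -0.34 ± 0.113 for Alpl and 0.14 ± 0.0982 for Nt5e, none of them called (adjusted p from 0.142 to 0.624). The abdominal change was 0.20 ± 0.147 for the phosphate transporter Slc20a1 (adjusted p = 0.503), -0.12 ± 0.124 for the inhibitor Mgp (adjusted p = 0.661) and 1.97 ± 0.851 for the inhibitor Ahsg, a liver gene (adjusted p = 0.208). Ahsg lay at 8.60 and 10.80 in abdominal high-phosphate arrays 3 and 4, the arrays with hepatocyte markers, and at or below 6.38 in every other array.

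Averaged over both segments, Ucp1 fell by 2.93 ± 0.27, Agpat2 fell by 2.04 ± 0.139 and Fkbp5 rose by 1.74 ± 0.12. Slc16a1, a carrier of lactate and ketone bodies, fell by 1.44 ± 0.17. The macrophage genes Cd163 (0.97 ± 0.186), Cd68 (0.78 ± 0.19) and Lyve1 (0.63 ± 0.11) and the clock genes Per1 (0.88 ± 0.156) and Tef (0.67 ± 0.124; -0.112 for its other probe set) rose. Pth1r (-0.36 ± 0.077), Phex (-0.50 ± 0.114) and Alpl (-0.38 ± 0.0767) fell, and Nt5e (0.25 ± 0.0669) and Axl, a receptor kinase of smooth muscle (0.18 ± 0.0465; thoracic change 0.26 ± 0.0682, adjusted p = 0.0604), rose. Limma called 2376 genes, 1005 higher and 1371 lower. Camera called 17 lists, 7 higher and 10 lower, 13 of them called by fry as well, and none held with an estimated correlation (lowest adjusted p = 0.0761). The count was 522 under a rule of unadjusted p and 1.5-fold, 1029 without the 5 abdominal arrays with lymphocyte markers, which left 1 abdominal high-phosphate array, and 0 with adipocyte covariates. The Axl call ended without thoracic high-phosphate array 3 (adjusted p = 0.063), and the Nt5e call without abdominal high-phosphate array 4, thoracic high-phosphate array 2 or thoracic chow array 1 (adjusted p up to 0.0617).

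Many genes were called in both segments. Of the genes called higher, 179 were shared, against 6.02 expected if the segments were independent, and of those called lower 216 were shared, against 12.1. Both changes came from the same fit with a shared spread per gene, so these expectations are only a rough guide. No gene was called in opposite directions. Across all genes, which are not independent replicates, Pearson's r between the changes was 0.481 and Spearman's rho was 0.416. Of the genes called higher in the abdominal segment 95.8% had the same sign in the thoracic segment, and of those called lower 95.2%.

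**Figure D3:**
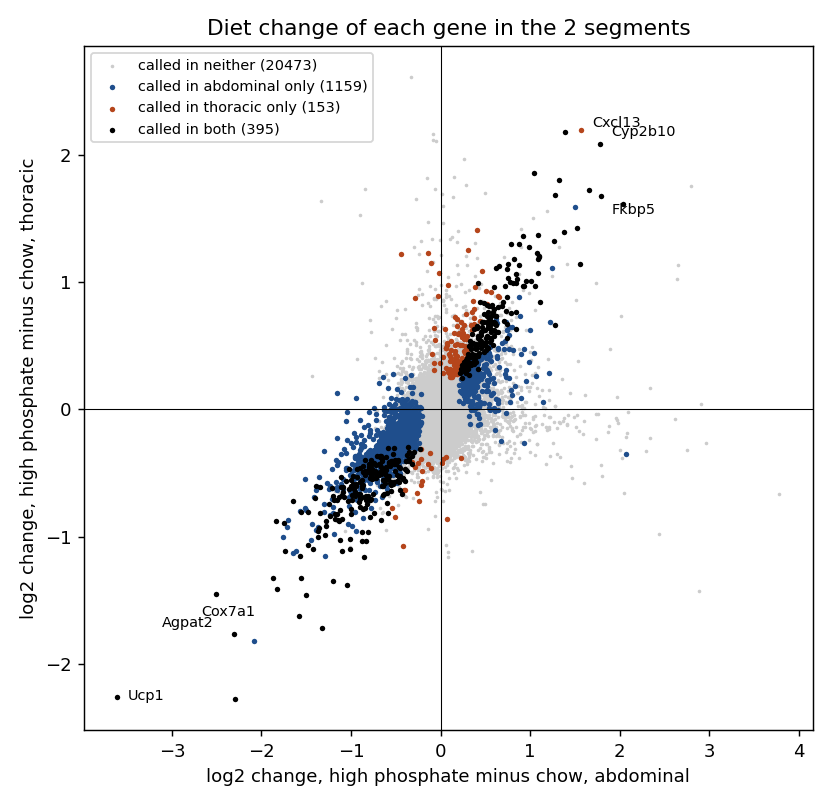
Log2 change of each gene under the high-phosphate diet in the abdominal (horizontal axis) and thoracic segment (vertical axis), with 1 point per gene, coloured by where limma called it. Ucp1, Agpat2 and Cox7a1 lie far to the lower left, and Fkbp5 and Cyp2b10 to the upper right.

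The difference between the segments was tested directly, as the abdominal minus the thoracic diet change. Among the genes with the smallest p were Cd248, a stromal glycoprotein (-0.93 ± 0.173), Krtap13 (0.60 ± 0.114), the sarcomere gene Lmod2 (-1.66 ± 0.337), Col3a1 (-0.79 ± 0.165) and Cox8b (-0.93 ± 0.196), each with an adjusted p of 0.705, and the liver gene Serpina1e (0.80 ± 0.201) had an adjusted p of 0.773. Limma called 0 genes, with 1217 at an unadjusted p under 0.05, where 1109 are expected by chance. Camera called 16 lists, 4 higher and 12 lower, while fry called 0 and none held with an estimated correlation (lowest adjusted p = 0.323). The mean difference was -0.33 for oxidative phosphorylation (adjusted p = 8.87e-17, and adjusted p = 0.323 with an estimated correlation) and -0.41 for extracellular matrix (adjusted p = 1.38e-13, and adjusted p = 0.323 with an estimated correlation). The count was 256 under a rule of unadjusted p and 1.5-fold, and 1 without abdominal high-phosphate array 3. It was 43, all higher, without the 5 abdominal arrays with lymphocyte markers, which left as the abdominal high-phosphate group only array 3, with a hepatocyte mean of 8.36, so that the spread came from the other groups.

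The segments were compared under chow as thoracic minus abdominal. The largest positive differences were those of cardiac muscle genes. Myl7, the atrial myosin light chain (probe set 17260236), was 9.28 ± 0.65 in the thoracic (n = 4) and 4.72 ± 0.29 in the abdominal arrays (n = 4), and the cardiac troponin gene Tnnt2 was 4.30 ± 0.277 higher. Snap25, a protein of synaptic vesicle fusion (probe set 17376822), was 10.84 ± 0.71 in the abdominal and 4.89 ± 0.16 in the thoracic arrays. Hoxc8, a patterning gene of the trunk, was lower in the thoracic segment (-1.22 ± 0.117).

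The other genes with the largest positive differences were the myosin Myh6 (3.64 ± 0.216), Ankrd1 (3.27 ± 0.167), the troponin Tnni3 (3.21 ± 0.243), the calcium pump inhibitor Sln (3.02 ± 0.299), and Csrp3 (3.01 ± 0.28). They also included Tnnc1 (2.99 ± 0.245), Myoz2 (2.38 ± 0.333) and Tecrl (2.36 ± 0.231), and all are expressed in striated or heart muscle. Most of those with the largest negative differences are neuronal or neuroendocrine. They were Glycam1, a ligand made by lymph node vessels (-5.00 ± 0.575), the neurofilament Nefl (-4.71 ± 0.406), Syt4 (-4.69 ± 0.397), and the neuropeptide Npy (-4.48 ± 0.311). The others were the acetylcholine receptor subunit Chrna3 (-4.33 ± 0.4), Dbh, which makes noradrenaline (-4.16 ± 0.376), the secretory granule genes Scg2 (-4.03 ± 0.448) and Chgb (-3.93 ± 0.314), and Gdap1 (-3.46 ± 0.404). The lower group mean was 4.01 to 5.72, below the array medians, for Myl7, Myh6, Sln, Csrp3, Tecrl, Snap25, Nefl, Syt4, Chrna3, Dbh, Scg2, Chgb and Gdap1. Signal over background is unknown at these levels, so their differences stand as lower bounds and their order is open.

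Of 15 sympathetic neuron and chromaffin genes 14 were lower in the thoracic segment (15 adjusted over the list alone), with a mean difference of -3.11 (adjusted p = 1.45e-32, and adjusted p = 0.044 with an estimated correlation). Of 14 cardiac muscle genes 9 were higher (10 adjusted over the list alone; adjusted p = 7.53e-17, and adjusted p = 0.00654 with an estimated correlation). Of 12 Schwann cell genes 6 were lower (8 adjusted over the list alone). They included Cdh19 (-2.70 ± 0.255) and the myelin gene Mal (-1.45 ± 0.144) (adjusted p = 2.58e-08, and adjusted p = 0.044 with an estimated correlation). Of 22 smooth muscle genes 12 were higher (20 adjusted over the list alone). They included Pln, a regulator of the calcium pump (1.67 ± 0.175), Casq2 (1.30 ± 0.172), Synpo2 (0.73 ± 0.115) and Smtn (0.82 ± 0.159) (adjusted p = 1.16e-14, and adjusted p = 0.219 with an estimated correlation). Pln and Casq2 are also genes of heart muscle. Of 23 Hox genes of paralog groups 6 to 13, which pattern the trunk and more posterior parts, 6 were lower (6 adjusted over the list alone). They included Hoxa9 (-0.87 ± 0.107), Hoxc6 (-0.67 ± 0.104) and Hoxc9 (-0.58 ± 0.0686) (adjusted p = 0.00128, and adjusted p = 0.0955 with an estimated correlation).

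Of 14 mesothelial genes Upk3b (1.17 ± 0.182), Lrrn4 (0.79 ± 0.205) and Bnc1 (0.62 ± 0.148) were higher (9 adjusted over the list alone; adjusted p = 2.42e-07, and adjusted p = 0.169 with an estimated correlation). Of 29 matrix genes 5 were higher (9 adjusted over the list alone). They were the elastic fibre genes Mfap4 (0.88 ± 0.176), Mfap5 (0.80 ± 0.193), Fbln5 (0.68 ± 0.163) and Loxl1 (0.60 ± 0.126), and the proteoglycan Vcan, named after its values were seen (0.61 ± 0.161) (adjusted p = 0.000471, and adjusted p = 0.569 with an estimated correlation). Of 15 cholesterol synthesis genes Sqle (-1.13 ± 0.229), Cyp51 (-0.58 ± 0.132), Sc5d (-0.50 ± 0.0983) and Srebf2 (-0.34 ± 0.0895) were lower (8 adjusted over the list alone; adjusted p = 4.95e-08, and adjusted p = 0.0946 with an estimated correlation). In the interferon list Stat2 was lower (-0.45 ± 0.107; 7 of 20 adjusted over the list alone; adjusted p = 2.77e-05, and adjusted p = 0.332 with an estimated correlation). In the skeletal muscle list the myosin Myh2 was lower (-1.17 ± 0.319; 1 adjusted over the list alone; adjusted p = 0.000628, and adjusted p = 0.569 with an estimated correlation). In the neutrophil and mast cell list the protease Cpa3 was lower (-0.51 ± 0.139; 1 adjusted over the list alone; adjusted p = 0.000646, and adjusted p = 0.569 with an estimated correlation). Camera also called 5 lists in which limma called 0 genes over all genes. These were oxidative phosphorylation (mean difference 0.21, 9 adjusted over the list alone; adjusted p = 2.42e-07), brown adipocyte (0.27; adjusted p = 0.0491), T and NK cell (-0.86; adjusted p = 0.000534), B and plasma cell (-0.70; adjusted p = 0.00279) and cell cycle (-0.16; adjusted p = 0.0461), the last 4 with 0 adjusted over the list alone, each with adjusted p = 0.569 with an estimated correlation, except cell cycle with 0.774. Of the calcification lists, Sost, an inhibitor of bone formation (0.76 ± 0.171, adjusted p = 0.0184), and Entpd1, which degrades ATP (0.45 ± 0.12, adjusted p = 0.0429), were higher in the thoracic segment.

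In all, limma called 1061 genes between the segments under chow, 391 higher and 670 lower in the thoracic segment, of which 45 and 252 differed at least 2-fold. Camera called 16 lists, 7 of them called by fry as well. The neuron, cardiac muscle and Schwann cell lists held with an estimated correlation, and the 26 lists not called by camera had adjusted p from 0.147 to 0.969. The count was 475 with adipocyte covariates, 571 with a lymphocyte covariate, 496 without the 5 abdominal arrays with lymphocyte markers, and 1795 at an adjusted p under 0.1. It was 500 without abdominal array 4, 702 without abdominal array 3, 695 without thoracic array 1 and 622 without thoracic array 4. With 1 array left out in turn, 13 of the 47 genes named for this comparison lost their call at least once (adjusted p up to 0.168). These were Bnc1, Lrrn4, Loxl1, Fbln5, Mfap5, Vcan, Stat2, Myh2, Cpa3, Sost, Entpd1, Cyp51 and Srebf2. The neutrophil and mast cell, B and plasma cell, cell cycle and brown adipocyte lists lost theirs too (adjusted p up to 0.434).

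Under the high-phosphate diet the segments differed, among others, in genes of heart muscle, nerve, smooth muscle, matrix, lymphocytes and adipocytes. The brown adipocyte mean was 8.29 in the thoracic and 7.54 in the abdominal group, and the pan-adipocyte mean 9.31 and 8.79. Ankrd1 was 4.36 ± 0.18 higher in the thoracic segment, Myl7 4.78 ± 0.278 and Myh6 4.55 ± 0.233 (both again lower bounds, with abdominal means of 4.59 and 5.14), Tnnc1 3.79 ± 0.265 and Pln 2.83 ± 0.189. Npy (-4.08 ± 0.336), Chgb (-3.69 ± 0.339), Gpm6b, a membrane protein of neurons and glia (-1.98 ± 0.192), the chloride channel regulator Clca3a1 (-1.73 ± 0.158) and the matrix protein Matn2 (-1.54 ± 0.149) were lower. All 22 smooth muscle genes were higher (22 adjusted over the list alone). They included Casq2 (1.83 ± 0.185) and Synpo2 (1.10 ± 0.124) (adjusted p = 7.78e-19, and adjusted p = 0.183 with an estimated correlation). Of 28 oxidative phosphorylation genes 27 were higher (27 adjusted over the list alone). They included Ndufa9 (0.75 ± 0.0902) (adjusted p = 7.59e-19, and adjusted p = 0.217 with an estimated correlation). Of 29 matrix genes 18 were higher (23 adjusted over the list alone). They included Vcan (1.59 ± 0.174), Col1a2 (1.10 ± 0.13; 0.465 for its other probe set) and Mfap4 (1.60 ± 0.19) (adjusted p = 1.63e-13, and adjusted p = 0.183 with an estimated correlation). Of 14 cardiac muscle genes 11 were higher (12 adjusted over the list alone; adjusted p = 1.15e-14, and adjusted p = 0.0127 with an estimated correlation).

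All 15 neuron genes were lower in the thoracic segment (15 adjusted over the list alone; mean difference -3.03; adjusted p = 1.67e-24, and adjusted p = 0.114 with an estimated correlation). Of 13 T and NK cell genes 8 were lower (10 adjusted over the list alone). They included the receptor genes Cd3g (-3.91 ± 0.915) and Cd4 (-2.22 ± 0.582) (adjusted p = 1.26e-06, and adjusted p = 0.297 with an estimated correlation). Of 12 B and plasma cell genes 7 were lower (10 adjusted over the list alone). They included Jchain (-2.89 ± 0.594) and Cd22 (-1.41 ± 0.399) (adjusted p = 1.29e-06, and adjusted p = 0.297 with an estimated correlation). Abdominal high-phosphate arrays 1, 2 and 4 are those with high lymphocyte markers.

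In all, limma called 3067 genes between the segments under high phosphate, 1680 higher and 1387 lower in the thoracic segment, of which 148 and 472 differed at least 2-fold. Of the genes called higher 261 were also called under chow, against 29.6 expected if independent, and of those called lower 552, against 41.9, with none opposite. These expectations too leave the shared spread per gene out of account. Camera called 19 of 42 lists, 11 higher and 8 lower, 18 of them called by fry as well. Of the 19 only cardiac muscle held with an estimated correlation. The count was 20 with adipocyte covariates. It was 403 with a lymphocyte covariate (162 higher, 241 lower), 466 without the 5 abdominal arrays with lymphocyte markers, which left 1 abdominal high-phosphate array (99 higher, 367 lower), and 1842 under a rule of unadjusted p and 1.5-fold (723 higher, 1119 lower). The balance turned in each of these 3, and without abdominal arrays 3 and 4 (1733 higher, 1845 lower). It was 2000 and 1849 without abdominal arrays 1 and 2, and 1695 and 2029 without thoracic arrays 1 and 3. The calls of Cd4 and Cd22 ended without 5 and 6 of the 7 arrays in turn (adjusted p up to 0.0888).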

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

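The splits for the difference between segments and all tests of the brown adipocyte and glucocorticoid patterns were chosen only after the results were seen.

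Each count of genes was set against other splits of the same arrays into groups of the same sizes. For the abdominal diet change 2 of 35 splits gave as many genes as the real 1554, and the highest other gave 1629, so chance cannot be excluded. That split set high-phosphate arrays 1, 2 and 4 and chow array 4 against the rest, which follows the lymphocyte markers, and with the lymphocyte lists as a covariate the real split gave 1245. For the thoracic diet change 1 of 35 splits, the real one, gave 548, with 11 the highest other. For the average 1 of 100 drawn splits gave 2376, with 255 the highest other. Chance is argued against for both, though ranking first is the most that 35 or 100 splits can show. For the difference between the segments 100 of 100 gave at least the real 0, as any split must, so this test decides nothing. Between segments 1 of 35 splits gave 1061 under chow, with 3 the highest other, and 1 of 35 gave 3067 under high phosphate, with 2877 the highest other. Chance is argued against under chow, with the same limit. Under high phosphate the split with 2877 set abdominal arrays 1, 2 and 4 against abdominal array 3 and the thoracic arrays. That split again follows lymphocyte markers, and it differs from the real one only in the place of abdominal array 3. The second highest other split gave 1. By rank chance is argued against here too, with the same limit. Since a split that follows lymphocyte markers comes close to the real count, that count cannot be laid to the segment alone.

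The fall of brown adipocyte genes under high phosphate was set against 3 technical explanations, all concerning what the pieces held. Over both segments the brown list fell further than the pan-adipocyte list, by -0.653 ± 0.0696 (SE over list members 0.251). An exact permutation within segments gave p = 0.000408, the smallest the 2450 permutations can give. The lists thus did not fall alike. Equal falls would follow from a lower share only if adipocytes alone made the list members, which need not hold. A lower share of adipocytes as the whole cause is therefore not decided by this test and stays open. A lower share of brown adipocytes alone stays open: the changes of 7 abundant members had an SD of 0.888 (exact permutation p = 0.000408, again the smallest possible), but shuffled diets do not test for equal falls, and probe sets of 1 gene differ as well, as for Dio2 (-1.017 and -0.317). Lymphoid tissue in the abdominal pieces as the whole cause is argued against by the thoracic fall of -0.882 ± 0.163, in arrays with low lymphocyte markers. Whether it adds to the abdominal fall is not tested by this and stays open. A mixture of fewer adipocytes with changed expression stays open too, as does an effect of the diet within the cells, both untested.

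The rise of glucocorticoid response genes was set against collection at another time of day and against other tissue. Lymphoid or liver tissue in the abdominal pieces as the whole cause is argued against by the thoracic rise of 0.746 ± 0.137. Whether such tissue adds to the abdominal rise is not tested by this and stays open. Thoracic chow array 4 itself had a hepatocyte mean of 6.65. The clock output genes moved apart from Arntl, Clock, Npas2, Nfil3 and Cry1 by 0.616 ± 0.141 (exact permutation within segments, p = 0.000408, the smallest possible), which is in line with collection at another time of day and leaves that open. The diet itself, through more glucocorticoid, stays open as untested, since no hormone values are given, and Per1 is in both lists.

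The differences between the segments under chow were set against neighbouring tissue in the pieces. Of 634 genes lower in the thoracic segment, list members left out, 81.9% varied with the neuron list among abdominal arrays, against 10.7% to 15.9% in 10000 random sets of matched level, which is in line with sympathetic ganglion tissue in the abdominal pieces. With the lymphocyte lists 15.9% varied, against 19.2% to 25.7%. At a given difference, though, genes that vary widely within a group are less readily called. The T and NK cell list had an SD of 0.932 in the abdominal chow arrays, so this test decides nothing and lymph node tissue stays open. Of 354 genes higher in the thoracic segment 26.6% varied with the cardiac list among thoracic arrays, against 14.1% to 22%, which is in line with heart muscle in the thoracic pieces as the source of part of them. A difference of the segments themselves, which the design names, stays open as untested.

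Of 567 Dixon tests in groups of 4 arrays 28 found an array far from the other 3, where chance gives about 28.4. In abdominal high-phosphate array 3 these were the list of Hox groups 6 to 13 (5.70), the macrophage list (7.85), Cryab (9.61), Dhcr7 (5.5), Dhrs9 (5.68), Hoxc8 (8.32), Synpo2 (8.43) and Tnni3 (6.13). In abdominal high-phosphate array 4 they were the fatty acid oxidation list (8.90), Ciart (7.60), Elovl5 (8.97), Pecam1 (9.70), Sc5d (8.13), Serpina1e (7.09) and Snap25 (10.72), and in array 1 Myh6 (4.84). In the abdominal chow group they were the neutrophil and mast cell list in array 2 (7.10), Glycam1 (8.95) and Tnnc1 (8.16) in array 1, and Tnni3 in array 4 (6.82). In the thoracic chow group they were the glucocorticoid list (7.59), the skeletal muscle list (6.53), Dpep1 (6.78), Rps9 (10.37), Srebf2 (6.42) and Thbs1 (6.05) in array 3, Cd34 in array 4 (9.53) and Ms4a4a in array 1 (6.16).

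Camera's test of the difference between the segments' diet changes called 16 lists, none with an estimated correlation (adjusted p from 0.323 to 0.774). The abdominal minus the thoracic change was 0.65 for B and plasma cells, 0.66 for T and NK cells, 0.12 for cell cycle, 0.18 for lymphatic endothelium, -0.30 for adventitial fibroblasts, -0.48 for brown adipocytes, and -0.32 for cardiac muscle. It was -0.39 for lipogenesis, -0.41 for extracellular matrix, -0.36 for fatty acid oxidation, -0.22 for hypoxia and glycolysis, -0.23 for matrix proteases and inhibitors, -0.33 for oxidative phosphorylation, -0.47 for pan-adipocyte genes, -1.03 for skeletal muscle and -0.38 for smooth muscle. With 1 array left out the skeletal muscle, T and NK cell, lipogenesis, matrix protease, cardiac muscle, lymphatic and cell cycle calls ended at least once (adjusted p up to 0.345).

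Among the 17824 probe sets without a single gene, which the comparisons of genes do not use, limma called 175 for the abdominal diet change, 31 for the thoracic one, 420 for their average, 239 between segments under chow and 845 under high phosphate.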

How the results depend on the processing

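The settings without 5 abdominal arrays, without abdominal high-phosphate arrays 3 and 4, and with a lymphocyte covariate were chosen only after the data were seen, and the cause of the changes below was not tested unless one is named. Quantile normalization, median centring, array weights, removal of dim genes, averaging of probe sets, the replicate block, fits of only the groups compared, a prior without trend and leaving out single arrays turned the direction of none of the named genes and, where run, none of the named lists. Of the named gene results, 2 lost their call with quantile normalization, 3 with median centring, 3 with array weights, 6 with the mean of probe sets, 10 with a prior without trend, 25 with only the groups compared, 43 under unadjusted p and 1.5-fold, and 29 with the replicate block. Besides those whose sign turned, the calls lost were 145 with adipocyte covariates, 85 without the 5 abdominal arrays, 29 with the lymphocyte covariate and 18 without abdominal high-phosphate arrays 3 and 4. Of 72 list results, 68 lost their call with an estimated correlation, 40 with fry, 30 with adipocyte covariates, 22 without the 5 abdominal arrays and 11 with the lymphocyte covariate. In the abdominal diet change the 11 include the hypoxia, endothelial, Wnt, cell cycle and B and plasma cell lists.

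Counts of called genes moved by over 1.5 times as follows. For the abdominal diet change the main count of 1554 became 1026 with only the 2 groups, which leaves fewer degrees of freedom, 812 under unadjusted p and 1.5-fold, 137 without the 5 arrays and 0 with adipocyte covariates. Leaving out 1 array gave 891 to 2249. For the thoracic one 548 became 907 with array weights, 237 with the replicate block, 992 at an adjusted p under 0.1, 990 with the lymphocyte covariate and 0 with adipocyte covariates. Leaving out 1 gave 209 to 541. For the average 2376 became 522 under unadjusted p and 1.5-fold, 1029 without the 5 arrays and 0 with adipocyte covariates, and leaving out 1 array gave 1957 to 2731. For the difference between segments 0 became 256 under unadjusted p and 1.5-fold and 43 without the 5 arrays, which leaves 1 abdominal high-phosphate array, and leaving out 1 array gave 0 to 1. Under chow 1061 became 475 with adipocyte covariates, 1795 at an adjusted p under 0.1, 496 without the 5 arrays and 571 with the lymphocyte covariate. Leaving out 1 gave 500 to 1369. Under high phosphate 3067 became 20 with adipocyte covariates, 1842 under unadjusted p and 1.5-fold, 466 without the 5 arrays and 403 with the lymphocyte covariate. Without 1 array it was 1695 to 4025.

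The adipocyte covariates fell under the diet themselves, so by construction they widen the errors, by a median of 3.01 times in the abdominal and 2.28 times in the thoracic segment. Fkbp5 went from 1.79 ± 0.163 to 1.60 ± 0.494 and Ucp1 from -3.61 ± 0.367 to -1.83 ± 1.06 in the abdominal segment. Signs turned with these covariates in the abdominal diet change for Il22ra2 (-0.987), Dgat2 (0.048), Hspd1 (0.229), Egln1 (0.078), Acta2 (0.049), Kdr (0.092), Rps9 (-0.059), Rps18 (-0.052), C1qb (-0.003), Clock (0.256), Alpl (0.279), Mgp (0.324), Slc20a1 (-0.355), Sod2 (0.099), Tek (0.22) and Slc2a1 (-0.232). Lists turned were those of fatty acid oxidation (0.006), hypoxia and glycolysis (0.137), smooth muscle (0.226), endothelium (0.093), ribosome (-0.114), macrophages (-0.28), cell cycle (-0.824), B and plasma cells (-2.135) and T and NK cells (-1.991). In the thoracic change they turned for Otop1 (0.003), Alpl (0.139), Cox8b (0.11) and the ribosome (-0.035), macrophage (-0.049) and skeletal muscle lists (-0.956), and in the average for Alpl (0.209), Cd68 (-0.75) and Sod2 (0.109). In the difference between segments the lists of fatty acid oxidation (0.088), B and plasma cells (-0.341), T and NK cells (-0.156), lipogenesis (0.041) and cell cycle (-0.151) turned, while that of brown adipocytes, itself a covariate, went to 0 by construction. Under chow the neutrophil and mast cell (0.025) and cell cycle lists (0.077) turned, and under high phosphate Cd22 (0.045) and the B and plasma cell list (0.155).

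Without the 5 arrays signs turned for Mgp (0.056), Slc20a1 (-0.028) and the cell cycle list in the abdominal change (-0.008), the difference between segments (-0.08) and the chow comparison (0.05). Without abdominal high-phosphate arrays 3 and 4, Ahsg turned (-0.178). With the lymphocyte covariate, which holds the T and NK cell and B and plasma cell lists and so brings their own changes near 0 by construction, Mgp (0.015) and the T and NK cell list (-0.023) turned in the abdominal change, the T and NK cell (-0.03) and cell cycle lists (-0.088) in the difference between segments, the B and plasma cell (0.042) and cell cycle lists (0.089) under chow, and the B and plasma cell list under high phosphate (0.01).

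The labels do not say that replicate numbers pair the arrays, and not every array correlated best with its own number. Across genes, r between deviations of arrays with the same number was 0.0308 to 0.122 between segments under high phosphate and 0.0295 to 0.0691 under chow, all above 0, and an array's own number matched best in 2 of 3 and 2 of 4 cases. Between diets r was -0.25 to 0.404 in the abdominal and 0.0256 to 0.17 in the thoracic segment, and the own number matched best in 1 of 4 and 2 of 3 cases. With the replicate block the calls that ended in the abdominal diet change were those of C1qb, Clock, Pth1r, Phex, Nt5e, Tef, Dhcr7, Hsph1 and the Wnt list. In the thoracic one they were those of Cxcl13, Lncbate10, Ndufa9, Elovl5, Rps18, Rps6, Usp2, Ciart, Zfp36, Retn, Sfrp2, Col3a1, Thbs1, Rpl14, Dio2, Cox8b and the heat shock list. In the difference between segments the lymphatic list lost its call, and under chow Bnc1, Cpa3, Srebf2, Lrrn4, Vcan and the cell cycle list did. The block ended no other call of a named gene or list. The depth of an array cannot be given, since no background values were available, so a difference whose lower group mean lies below the array medians is open to being larger.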

Other observations

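The list behind the food intake test in this part was added after the data were seen, and the test itself was chosen before its result was known.

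Several stress and mast cell genes changed in the abdominal segment while their lists were not called. Sod2, the mitochondrial superoxide dismutase, fell by 1.11 ± 0.14 (adjusted p = 0.000211), and by 0.85 ± 0.103 over both segments, while the oxidative stress list, with 3 of 17 members called higher and 2 lower in the abdominal segment, had an adjusted p of 0.838 in the abdominal and 0.0589 in the thoracic segment. Calr, a chaperone of the endoplasmic reticulum, fell by 0.45 ± 0.0893 (average -0.40 ± 0.0657), and the unfolded protein list, with 1 of 18 members called higher and 2 lower, had an adjusted p of 0.165 and 0.0718. The mast cell proteases Cma1 (-0.53 ± 0.111), Mcpt4 (-0.77 ± 0.169; average -0.65 ± 0.124) and Cpa3 (-0.62 ± 0.139) fell in the abdominal segment, where the neutrophil and mast cell list had an adjusted p of 0.446, and the Cpa3 call ended without chow array 1 (adjusted p = 0.0538).

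In the thoracic segment, where the cholesterol, Wnt and matrix lists were not called, Hmgcs1 (-1.16 ± 0.145) and Insig1 (-1.12 ± 0.154) fell and Fdft1, the squalene synthase gene, rose (0.49 ± 0.103). Sfrp2 (-0.61 ± 0.146; -0.266 for its other probe set) and Col3a1 (-0.60 ± 0.121) fell, and Thbs1, a matrix glycoprotein that activates TGF-beta, rose (0.89 ± 0.19). The calls of Fdft1, Sfrp2, Col3a1 and Thbs1 each ended with some single array left out (adjusted p up to 0.17).

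Lower lipogenesis and higher glucocorticoid response together may reflect reduced food intake, a hypothesis formed on these data. Genes raised by FoxO factors in fasting were tested, 17 of them measured. Their mean change over both segments was 0.188 (camera p = 3.67e-05, and p = 0.0284 with an estimated correlation), with 0.156 in the abdominal (p = 0.00186, and p = 0.0839 with an estimated correlation) and 0.219 in the thoracic segment (p = 1.07e-05, and p = 0.0211 with an estimated correlation). Over both segments 6 members rose, namely Sesn1 (0.65 ± 0.0842), Gabarapl1 (0.57 ± 0.118), Klf15 (0.52 ± 0.134), Cited2 (0.49 ± 0.09), Foxo3 (0.36 ± 0.081) and Cdkn1b (0.28 ± 0.0652), while Ccng2 fell (-0.26 ± 0.0752). The rise of the listed genes goes with the hypothesis, but Klf15 and other members also respond to glucocorticoid. Neither food intake nor body weight is given. The list leaves out Depp1, named above as a FoxO target, which rose in the abdominal segment. It also leaves out Pdk4, a kinase that spares glucose, which fell there. The fatty acid oxidation list was called lower in both segments. Reduced food intake thus stays open.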
